A study of Mus musculus with 9 samples.

How the data were processed

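Total RNA of mouse hearts was sequenced at 3 stages, E18, 3d and 8w, with 3 libraries per stage and 9 in all. The labels give wild type animals and heart tissue, and also use the word cardiocytes. They name the Qiagen RNeasy kit and the SMARTER library kit. Sex, strand setting, sequencing batch, annotation release and the circRNA caller are not given in the sources used here. The submitters' processing notes name cutadapt 1.9.1 for trimming, HISAT2 2.0.4 for alignment, Cuffdiff for quantification, and the builds GRCm38 and mm10.

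The FPKM values of the coding and lncRNA tables were computed by the authors per gene or transcript and library, per the file headers and the processing notes in the labels. The estimated counts in the same deposited tables were fragments multiplied by 1 factor per library: low values lay at whole multiples of a step between 0.80326 and 1.11567, and 94.2% to 94.7% of low values were whole within 0.01 after division. The circRNA counts were deposited by the authors as back-splice junction reads per library, per the file headers. A further 9 per-sample columns of the circRNA table could not be matched to libraries and were left out. Of 22481 coding gene identifiers 97.0% were found in GENCODE vM21 (GRCm38), and 99.9% of those overlapped the locus given there. Of 3549 exonic circRNAs 99.6% had both ends at exon edges.

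Coding entries were summed from 22564 to 22481 genes, of which 5127 were 0 in all libraries, and 31549 lncRNA transcripts were summed to 26341 genes. Of 4610 circRNAs 620 were listed as sense overlapping and 392 were intronic. Each library held 12196925 to 15613286 estimated fragments. The 2676 to 4494 junction reads per library limited precision for circRNAs, of which 2148 were seen in 1 library and 124 in all 9.

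Coding genes with a mean FPKM of at least 1 (11930) and lncRNA genes with at least 0.5 (3635) were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2 FPKM plus 1. All 9 libraries were in 1 fit, leaving 6 residual degrees of freedom. The plan named edgeR if the column held counts; the estimated counts carried a factor per library and were not whole, so FPKM were kept and edgeR on the recovered fragments became an alternative. CircRNAs with at least 10 reads in sum (626) were tested with edgeR 4.0.16 quasi-likelihood and TMM factors. Comparisons were 3d against E18, 8w against 3d and 8w against E18, and a call was a Benjamini-Hochberg adjusted p under 0.05. Ratios of circRNA reads are relative to all junction reads of the stage, with 95% counting intervals; 3 reads over the group stand for a count of 0. Single library-level values were compared with exact permutation tests.

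Of 34 gene lists written beforehand, 30 had at least 4 tested members. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Camera compares the members of a list with the other tested genes, and fry compares them with no change. A list adjusted p without a named test is from camera with the preset correlation. The lists covered the fetal cardiac program, adult sarcomere and energy transfer, calcium handling, potassium channels, mitosis, DNA replication, fatty acid oxidation, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation, mitochondrially encoded genes, extracellular matrix, imprinted growth genes, let-7 targets, ribosomal proteins, immediate early genes, interferon response, circadian clock and sex-linked genes. The other lists were markers of cardiomyocytes, atrium, ventricle, fibroblasts, endothelium, endocardium, smooth muscle, epicardium, macrophages, lymphocytes, erythroid cells, neural cells, adipocytes, skeletal muscle and lung epithelium. Counts were also made with p-values adjusted over the list alone.

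Named coding genes were the 8 largest rises and falls per comparison with adjusted p under 0.05, a mean FPKM of at least 10 in the higher stage and no overlap of replicates, and 2 to 4 genes per list. Named lncRNAs were the 5 largest rises and falls with at least 2 FPKM plus a preset group, and named circRNAs the 5 largest of each direction. Names made of clone numbers were left out, and some genes that met the rule are not reported here. Samples, comparisons, lists, this rule and most alternatives were fixed before the data were examined. The alternatives were the pseudocount, filters, quantile normalization, median centring, limma without trend, fits of 2 stages, a replicate block, leaving out each library, a 2-fold minimum, DESeq2 1.42.0, and library size without TMM.

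The methods were tested on simulated data with known changes. These were placed in a minority of features and in random directions, without a shift of the median gene. In the real data 3153 to 7761 of 11930 coding genes were called, so recovery and false calls there may differ from those given here. At 2-fold, 80%, 77.2% and 81.9% of changed coding genes were called in the 3 comparisons, with 5.6%, 4.9% and 4.9% false calls. For lncRNAs, 3.6%, 4.3% and 4.2% were called at 2-fold and 38.2%, 40.6% and 38.2% at 4-fold. Their false calls were 8.9%, 6.5% and 8.7% (95% intervals 5.9 to 12.7, 4.1 to 9.8 and 5.8 to 12.5), against a nominal 5%. For circRNAs, 1.5%, 0.5% and 1.5% were called at 2-fold, 14%, 23% and 16.5% at 4-fold, and 42.5%, 36% and 37% at 8-fold, with 0.9%, 1.7% and 2.7% false calls. A shifted list was called by camera, and 0 of 29 other lists. Genes were drawn independently there, whereas the estimated correlation in the real data was 0.456 for the mitosis list. The 0 of 29 therefore does not show how camera with its preset correlation behaves on these data. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.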

Results

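RNA from mouse hearts was sequenced at 3 stages: embryonic day 18 (E18), 3 days after birth (3d) and 8 weeks of age (8w). Each stage had 3 libraries, called biological replicates in the labels, which do not state that each came from a separate animal. The p-values below therefore measure spread between samples. The series asked how transcript levels differ between embryonic, neonatal and adult hearts, beside a study of circular DNA in the same organ. Coding genes and long non-coding RNAs (lncRNAs) were given as FPKM (fragments scaled by transcript length and library size), and circular RNAs (circRNAs, closed by a back-splice) as counts of junction reads. The tables held 22481 coding genes, 26341 lncRNA genes and 4610 circRNAs.

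Each library held between 12196925 and 15613286 estimated fragments over the coding and lncRNA tables, and between 2676 and 4494 back-splice junction reads. Junction reads per M (mega) fragments were 287.9 ± 17.3 at E18, 252.5 ± 42.8 at 3d and 294.4 ± 26.3 at 8w (SD, n = 3). Exact two-sided permutation tests of these gave p = 0.3 for 3d against E18, 0.2 for 8w against 3d and 0.7 for 8w against E18, where 3 libraries against 3 cannot go below 0.1. The 20 most abundant coding genes of a library held 11.1% ± 0.5 of its coding fragments at E18, 17.2% ± 0.9 at 3d and 15.2% ± 0.5 at 8w (SD, n = 3). The mitochondrial mt-Co1, with 623305 to 742697 fragments at 3d, was listed at 0 in every library of 8w. The lower share at 8w than at 3d is therefore not read as a change. One library stood apart: 3d replicate 1 had 24.6% of its FPKM in lncRNAs and 219.4 junction reads per M fragments. The lncRNA Xist, made by an inactive X chromosome, lay at 202.5 FPKM in it. That value alone does not give the sex of the sample.

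On the deposited FPKM scale the median coding gene was lower at the later stage of each comparison. The median log2 fold change of the 11930 tested coding genes was −0.154 for 3d against E18, −0.177 for 8w against 3d and −0.324 for 8w against E18. Single-gene values below are on that deposited scale and are to be read against these medians.

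At 3d against E18, an interval that spans birth, genes of cell division and of glucose use were lower, and genes that burn fat were higher. Ucp3, a mitochondrial carrier induced with fat use, rose from 0.256 ± 0.15 to 8.15 ± 2.58 FPKM between E18 and 3d (SD, n = 3). Its log2 fold change was 2.83 ± 0.39 (SE, adjusted p = 0.0011). Slc16a3, a lactate exporter (chromosome 11, 120948480 to 120960868, GRCm38), fell from 27.3 ± 1.92 to 3.14 ± 1.63 FPKM (log2 fold change −2.84 ± 0.30 SE, adjusted p = 0.000354). The glucocorticoid-responsive repressor Klf9 rose from 5.04 ± 0.115 to 23.5 ± 2.49 FPKM (log2 fold change 2.01 ± 0.10 SE, adjusted p = 8.21e-06). Myh6, the fast adult myosin heavy chain of the mouse ventricle, rose 2.72-fold to 3080 ± 748 FPKM, and Myh7, its slow fetal counterpart, fell 1.80-fold to 1090 ± 280 FPKM (SD, n = 3).

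Further large rises at 3d included Lgals4 (2.39 ± 0.31 on the log2 scale), the desaturase Scd4 (1.95 ± 0.19), the kinase Mapk10 (1.89 ± 0.20), Art3 (1.73 ± 0.11) and the copper carrier ceruloplasmin, Cp (1.69 ± 0.13). Among the large falls were the incretin receptor Gipr (−2.15 ± 0.19), the mitochondrial adenylate kinase Ak4 (−2.02 ± 0.17), the oxygen sensor Egln3 (−1.89 ± 0.18) and cyclin E2, Ccne2 (−1.78 ± 0.18). Each of these values is a log2 fold change with its SE over 3 libraries per stage, and the adjusted p ranged from 2.63e-05 for Art3 to 0.000915 for Lgals4.

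Metabolic lists moved in opposite directions at 3d. Of 26 fatty acid oxidation genes, 16 rose and 0 fell (18 rose and 1 fell adjusted over the list alone), with the uncoupling protein Ucp3 at 2.83 ± 0.39 and the malonyl-CoA decarboxylase Mlycd at 0.86 ± 0.09 on the log2 scale. Of 22 glycolysis genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with Pgam1 at −2.02 ± 0.15, the glucose transporter Slc2a1 at −1.96 ± 0.10 and hexokinase 2, Hk2, at −1.35 ± 0.20. The list tests gave adjusted p = 2.93e-13 for fatty acid oxidation and 7.76e-08 for glycolysis. The latter had adjusted p = 0.143 with an estimated correlation, and the former 0.0346. Of 11 genes encoded on mitochondrial DNA, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with mt-Co2 at 2.01 ± 0.28 and mt-Nd1 at 1.34 ± 0.15 (list adjusted p = 3.13e-08, and 0.0354 with an estimated correlation). In this list mt-Atp6 was listed at 0 in 3d replicate 1, beside 1025 and 1283 fragments in 3d replicates 2 and 3. Values of single mitochondrial genes are therefore uncertain at 3d as well. Of 45 nuclear-encoded oxidative phosphorylation genes 1 rose and 5 fell (0 and 2 adjusted over the list alone; 1 and 0 after median centring; list adjusted p = 0.437), and their median of −0.18 turned to 0.01 after quantile normalization. Likewise 5 of 23 tricarboxylic acid cycle genes fell and 0 rose (5 and 0 adjusted over the list alone; list adjusted p = 0.211), and 0 fell after quantile normalization.

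Proliferation genes were lower at 3d. Of 30 mitosis genes 28 fell (29 adjusted over the list alone), among them cyclin A2, Ccna2, at −1.29 ± 0.19 and topoisomerase Top2a at −1.13 ± 0.19. The list had adjusted p = 4.66e-12, and adjusted p = 0.154 with an estimated correlation. Of 30 DNA replication genes 29 fell (30 adjusted over the list alone), among them Rrm2, a subunit of ribonucleotide reductase, at −1.41 ± 0.18 (list adjusted p = 2.53e-12; adjusted p = 0.0767 with an estimated correlation). Of 43 cytosolic ribosomal protein genes 28 fell (33 adjusted over the list alone; 17 after quantile normalization and 16 after median centring), with Rps19 at −0.90 ± 0.12 (list adjusted p = 7.76e-08; adjusted p = 0.198 with an estimated correlation). These genes have many processed pseudogenes, so their single values are uncertain. Of 15 imprinted growth genes 10 fell (12 adjusted over the list alone; 5 after median centring), with the adaptor Grb10 at −0.90 ± 0.08 (list adjusted p = 0.00292; adjusted p = 0.154 with an estimated correlation). Of 9 fetal RNA-binding and let-7 target genes 5 fell (5 adjusted over the list alone), with the chromatin protein Hmga2 at −1.37 ± 0.14 (list adjusted p = 0.00313; adjusted p = 0.0767 with an estimated correlation).

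Contractile and rhythm genes changed in part. Of 18 adult sarcomere and energy transfer genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; 8 and 0 with edgeR), with the M-band protein Myom2 at 1.00 ± 0.10 (list adjusted p = 0.0021; adjusted p = 0.0767 with an estimated correlation). Of 14 fetal cardiac program genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; 1 and 1 after quantile normalization, after median centring and with edgeR; list adjusted p = 0.793). Calcium handling had 3 of 19 risen and 2 fallen (3 and 2 adjusted over the list alone; 5 and 0 after median centring, 6 and 1 with edgeR; list adjusted p = 0.0196; adjusted p = 0.154 with an estimated correlation), with the calcium release channel Ryr2 at 0.58 ± 0.08. Potassium channels had 3 of 16 risen and 1 fallen (3 and 1 adjusted over the list alone; 5 and 0 after median centring, 7 and 1 with edgeR; list adjusted p = 0.00719; adjusted p = 0.143 with an estimated correlation). Of 15 circadian clock genes 7 rose and 0 fell (10 and 0 adjusted over the list alone), with Nr1d2 at 0.77 ± 0.15 and Per3 at 1.00 ± 0.23 (list adjusted p = 1.69e-06, and 0.0354 with an estimated correlation). The hour of collection is not given in the sources used here. The interferon list had 2 of 18 risen (2 adjusted over the list alone; list adjusted p = 0.0021; adjusted p = 0.334 with an estimated correlation). With fry the calcium handling, potassium channel and interferon lists did not pass (adjusted p = 0.283, 0.116 and 0.373). The immediate early and heat shock list had 3 of 14 fallen (3 adjusted over the list alone; list adjusted p = 0.205), among them Ier3 at −1.21 ± 0.18. The extracellular matrix list had 4 of 34 fallen (4 adjusted over the list alone; list adjusted p = 0.589), with versican, Vcan, at −0.57 ± 0.10. Its median of −0.09 turned to 0.15 after quantile normalization.

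Markers of cell types were measured beside these groups. Of 16 endothelial markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; 10 and 0 with edgeR), with Ly6c1 at 1.32 ± 0.09 (list adjusted p = 4.79e-06; adjusted p = 0.154 with an estimated correlation). Of 7 epicardial markers 5 fell (6 adjusted over the list alone; 2 after median centring), with Tbx18 at −0.73 ± 0.13 (list adjusted p = 0.0156; adjusted p = 0.14 with an estimated correlation). Of 9 erythroid markers 5 fell (6 adjusted over the list alone), with embryonic globin Hbb-y from 4.94 ± 1.44 to 0.502 ± 0.183 FPKM (list adjusted p = 0.00544; adjusted p = 0.294 with an estimated correlation). Adult globin Hbb-bs fell from 2770 ± 81.7 to 803 ± 77.7 FPKM, a value that near-identical globin copies could share. Cardiomyocyte markers had 3 of 11 risen and 2 fallen (4 and 2 adjusted over the list alone; 5 and 0 after median centring, 6 and 0 with edgeR; list adjusted p = 0.0102; adjusted p = 0.117 with an estimated correlation). Fibroblast markers had 2 of 14 risen (2 adjusted over the list alone; list adjusted p = 0.0274; adjusted p = 0.531 with an estimated correlation), with Dpep1 at 1.06 ± 0.15. Of the 11 macrophage markers 0 passed singly (0 adjusted over the list alone; list adjusted p = 0.0176; adjusted p = 0.198 with an estimated correlation). With fry the fibroblast and macrophage lists did not pass (adjusted p = 0.54 and 0.287). No list call was made for the atrial markers (0 of 8, median 0.32 and mean −0.11) or the ventricular markers (2 risen and 2 fallen of 9, median −0.12, turning to 0.01 after quantile normalization). The same held for the endocardial and valve markers (1 fallen of 8, median −0.01, turning to 0.14 after quantile normalization), the smooth muscle and pericyte markers (2 risen and 4 fallen of 12, 4 and 1 after median centring, median 0.04 and mean −0.06), the neural markers (1 risen and 1 fallen of 4) and the Y-linked genes (0 of 4). The adipocyte and endothelial fatty acid binder Fabp4 rose by 1.20 ± 0.21. The skeletal myosin light chain Mylpf had a log2 fold change of −0.61 ± 0.25 (adjusted p = 0.0908), and of the lung genes Scgb1a1 was 0 FPKM at E18 and 18.4 ± 17.1 at 3d. Adipocyte, skeletal muscle, lung epithelium and lymphocyte markers had 1, 1, 3 and 0 tested members and no list test.

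In total 3153 of 11930 coding genes passed limma-trend with Benjamini-Hochberg adjusted p under 0.05 at 3d against E18, 596 higher and 2557 lower, and 19 of 30 lists passed camera. The split was 1089 higher and 1160 lower after quantile normalization, 1146 and 997 after median centring, and 1376 and 1260 with edgeR on the estimated counts. Without E18 replicate 1, 2 or 3 the count was 2016, 1961 or 1823. Only 3 lists kept their call with an estimated correlation, those of fatty acid oxidation, mitochondrially encoded genes and the circadian clock.

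Among lncRNAs, Neat1, the scaffold of nuclear paraspeckles (chromosome 19, 5824708 to 5845478), rose from 25.9 ± 3.51 to 90.3 ± 19.5 FPKM (SD, n = 3; log2 fold change 1.75 ± 0.18 SE, adjusted p = 0.0042). Rian, from the imprinted Dlk1 to Dio3 region, fell from 145 ± 15.1 to 69.5 ± 0.235 FPKM (adjusted p = 0.0113), a call that ended without E18 replicate 3. H19, the imprinted neighbour of Igf2 (chromosome 7, 142575529 to 142578143), fell from 1410 ± 130 to 789 ± 134 FPKM (adjusted p = 0.0303), a call that ended under median centring and without E18 replicate 1, 2 or 3 or 3d replicate 2 or 3. Meg3 had a log2 fold change of −0.21 ± 0.31, Mirg −0.40 ± 0.17, Malat1 0.52 ± 0.16, Kcnq1ot1 −0.47 ± 0.12, Airn −0.08 ± 0.17 and Xist 0.41 ± 0.32, none passing limma. Other large changes came from lncRNA entries that carry the name of a coding or mitochondrial gene and could share its reads, such as P4ha1 (−3.59 ± 0.37), Oxct1 (−1.37 ± 0.20) and the mitochondrial Cytb (2.11 ± 0.31). Of 3635 lncRNA genes 156 passed limma, 75 higher and 81 lower, which became 184 and 44 under median centring. Entries overlapping a coding exon in sense, which could share its reads, made up 1118 of those tested and 49 of those called. The count was 27, 27 or 22 without E18 replicate 1, 2 or 3, and 95, 56 or 52 without 3d replicate 1, 2 or 3.

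Two-sided edgeR quasi-likelihood tests called 2 of 626 circRNAs at 3d against E18, both higher, with 47 at an unadjusted p under 0.05 and 2 called by DESeq2. The first, from titin (Ttn), whose product is the molecular spring of the sarcomere, joined exon 120 back to exon 87 of ENSMUST00000099981.8 (chromosome 2, 76857904 to 76881839). It rose from 17 to 62 junction reads summed over 3 libraries, 4.03-fold relative to all junction reads (95% counting interval 2.33 to 7.36, adjusted p = 5.17e-05). The second, listed under Myh6 as overlapping the gene in sense (chromosome 14, 54953322 to 54983710), rose from 15 to 68 reads, 5.01-fold (2.84 to 9.44, adjusted p = 6.52e-05). Its ends lie within Myh6 (54941921 to 54966927) and its neighbour Myh7 (54970684 to 54994626), which are similar in sequence, so its identity is uncertain. Intervals and floors cover counting error only.

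**Figure D1:**
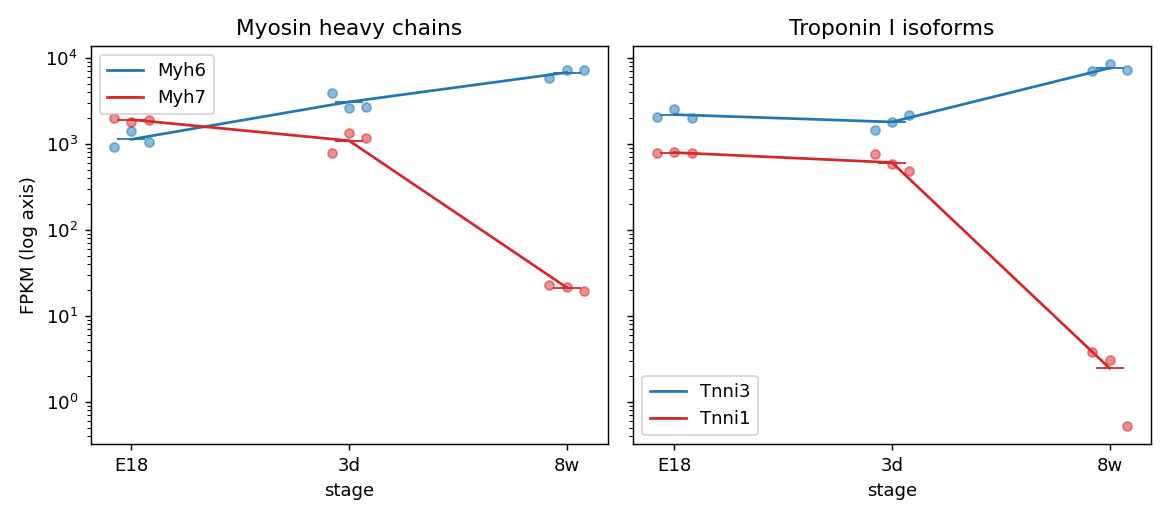
FPKM on a log axis by stage for myosin heavy chains Myh6 and Myh7 (left) and troponin I isoforms Tnni3 and Tnni1 (right); dots are the 3 libraries of a stage and lines join the means. Myh7 drops from 1920 at E18 to 21.4 at 8w while Myh6 goes from 1130 to 6770, and Tnni1 drops from 794 to 2.47 while Tnni3 goes from 2190 to 7620.

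Between 3 days and 8 weeks the fetal isoforms Tnni1 and Myh7 and the growth factor gene Igf2 fell to low levels. Tnni1, the slow skeletal troponin I of the fetal heart (chromosome 1, 135779434 to 135810989), fell from 608 ± 143 to 2.47 ± 1.72 FPKM (SD, n = 3; log2 fold change −7.59 ± 0.35 SE, adjusted p = 5.97e-08). Myh7 (chromosome 14, 54970684 to 54994626) fell from 1090 ± 280 to 21.4 ± 1.72 FPKM (log2 fold change −5.57 ± 0.17 SE, adjusted p = 4.47e-09). Cardiac troponin I, Tnni3, rose from 1800 ± 352 to 7620 ± 767 FPKM (log2 fold change 2.09 ± 0.17 SE, adjusted p = 2.86e-06). The fetal growth factor Igf2 fell from 473 ± 141 to 14.0 ± 1.81 FPKM (log2 fold change −4.95 ± 0.18 SE, adjusted p = 1.36e-08).

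The largest rises at 8w were the tubulin Tuba8 (5.11 ± 0.21 on the log2 scale), the muscle ribosomal protein Rpl3l (4.95 ± 0.23), the ADP-ribosyltransferase Art1 (4.79 ± 0.13), the carboxylesterase Ces1d (4.54 ± 0.20), the actin-binding Xirp2 (4.32 ± 0.12), Lrtm1 (4.32 ± 0.15), the retinoid receptor Rxrg (4.13 ± 0.12) and Cd74, the invariant chain of MHC class II (4.09 ± 0.19). The largest falls after Tnni1 and Myh7 were Dlk1 (−5.03 ± 0.14), Mest (−5.00 ± 0.23), Igf2, the zinc finger factor Plagl1 (−4.85 ± 0.11) and the Y-linked Eif2s3y (−4.55 ± 0.40). Adjusted p was at most 6.18e-08 for these except Eif2s3y (4.97e-06). The mitochondrial mt-Co1 was 34600 ± 4310 FPKM at 3d and listed at 0 in all 3 libraries at 8w, and mt-Nd3, mt-Nd4, mt-Nd4l, mt-Co3 and mt-Atp6 were listed at 0 in 8w replicate 1.

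Every one of 18 adult sarcomere and energy transfer genes rose (18 adjusted over the list alone), and 15 did after quantile normalization. Mitochondrial creatine kinase Ckmt2 went from 73.6 ± 10.1 to 1020 ± 135 FPKM and myoglobin, Mb, from 1370 ± 86.7 to 7740 ± 447 FPKM (list adjusted p = 8e-12, and 0.00767 with an estimated correlation). All 26 fatty acid oxidation genes rose (26 adjusted over the list alone; 22 after quantile normalization), with lipoprotein lipase, Lpl, at 2.14 ± 0.13 and Hadhb at 1.59 ± 0.10 (list adjusted p = 4.36e-14, and 0.0161 with an estimated correlation). Of 45 oxidative phosphorylation genes 42 rose and 0 fell (42 and 0 adjusted over the list alone; 29 after quantile normalization), with Ndufb9 at 1.35 ± 0.08 (list adjusted p = 1.48e-16; adjusted p = 0.0727 with an estimated correlation). Of 23 tricarboxylic acid cycle genes 21 rose (22 adjusted over the list alone), with the pyruvate carrier Mpc1 at 1.87 ± 0.11 and Ogdh at 1.69 ± 0.09 (list adjusted p = 8e-12; adjusted p = 0.0776 with an estimated correlation). Glycolysis genes split, with 10 risen and 8 fallen of 22 (10 and 8 adjusted over the list alone; 10 and 5 after median centring, 8 and 9 after quantile normalization; list adjusted p = 0.106): Hk2 was at 2.35 ± 0.20, the insulin-responsive transporter Slc2a4 at 2.15 ± 0.12 and Aldoc at −2.22 ± 0.15. Potassium channels had 11 risen and 3 fallen of 16 (11 and 3 adjusted over the list alone), with Kcnk3 at 2.29 ± 0.16 and Kcne1 at −2.53 ± 0.21 (list adjusted p = 9.5e-05; adjusted p = 0.0727 with an estimated correlation). Calcium handling had 10 risen and 8 fallen of 19 (10 and 8 adjusted over the list alone; list adjusted p = 0.111), with the calcium pump Atp2a2 at 1.85 ± 0.11 and the T-type channel Cacna1g at −1.52 ± 0.24. Fetal cardiac program genes had 1 risen, Acta1 at 2.66 ± 0.31, and 7 fallen of 14 (1 and 7 adjusted over the list alone; list adjusted p = 0.0787). Fry, which compares with no change, called the fetal list lower (adjusted p = 0.00015).

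All 30 mitosis genes and all 30 DNA replication genes fell (30 and 30 adjusted over the list alone; 28 of the replication genes after quantile normalization). Ccna2 went from 40.1 ± 8.23 to 1.56 ± 0.462 FPKM and Rrm2 from 37.5 ± 5.78 to 2.25 ± 0.525 FPKM. The lists had adjusted p = 1.48e-16 and 1.07e-09, and adjusted p = 0.112 and 0.0776 with an estimated correlation. Imprinted growth genes had 13 fallen and 2 risen of 15 (13 and 2 adjusted over the list alone; list adjusted p = 2.14e-06; adjusted p = 0.0727 with an estimated correlation). Of 9 fetal RNA-binding and let-7 target genes 7 fell (7 adjusted over the list alone), with the mRNA-binding Igf2bp3 at −3.40 ± 0.12 (list adjusted p = 0.0106; adjusted p = 0.0776 with an estimated correlation). Extracellular matrix genes had 25 fallen and 5 risen of 34 (25 and 5 adjusted over the list alone), with periostin, Postn, from 384 ± 42.1 to 32.0 ± 9.57 FPKM and fibrillin 2, Fbn2, at −3.76 ± 0.15 (list adjusted p = 0.000156; adjusted p = 0.527 with an estimated correlation). Ribosomal protein genes had 18 fallen and 1 risen of 43 (18 and 1 adjusted over the list alone; list adjusted p = 0.0787). The number fallen was 30 after quantile normalization (median −0.49) and 9 after median centring (median −0.07), and Rpl3 was at −1.37 ± 0.11. Of 11 genes on mitochondrial DNA 2 passed as lower (2 adjusted over the list alone; 5 after quantile normalization; list adjusted p = 0.121). They were mt-Nd1 at −0.59 ± 0.15, a call that ended under median centring, and mt-Co1, whose listing at 0 is not read as a fall.

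Macrophage markers rose in 9 of 11 cases (10 adjusted over the list alone), with lysozyme, Lyz2, from 12.2 ± 1.06 to 88.3 ± 21.1 FPKM and the scavenger receptor Cd163 at 2.25 ± 0.14 (list adjusted p = 1.64e-05; adjusted p = 0.0727 with an estimated correlation). Of 18 interferon response genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), with the MHC class I gene H2-K1 at 2.43 ± 0.14 (list adjusted p = 2.82e-05; adjusted p = 0.248 with an estimated correlation). Cardiomyocyte markers had 7 risen and 1 fallen of 11 (7 and 2 adjusted over the list alone; 4 and 3 after quantile normalization), with Cmya5 at 2.26 ± 0.08 (list adjusted p = 0.00653; adjusted p = 0.0776 with an estimated correlation). Epicardial markers had 6 fallen of 7 (6 adjusted over the list alone), with Tbx18 at −1.60 ± 0.13 (list adjusted p = 0.0309; adjusted p = 0.121 with an estimated correlation). Fibroblast markers went both ways, 5 risen and 4 fallen of 14 (5 and 4 adjusted over the list alone; list adjusted p = 0.163), with gelsolin, Gsn, at 2.30 ± 0.13 and collagen Col1a1 at −2.23 ± 0.21. No call was made for the endothelial list (4 risen and 6 fallen of 16, 4 and 2 after median centring, median −0.18 and mean 0.01, Aqp1 at 1.89 ± 0.17 and Cdh5 at −0.79 ± 0.11), the smooth muscle and pericyte list (5 and 3 of 12, Rgs5 at 1.52 ± 0.09) or the erythroid list (1 and 6 of 9, 1 and 3 after median centring). The same held for the endocardial list (1 and 5 of 8), the ventricular list (3 and 5 of 9, 3 and 3 after median centring, Hey2 at −3.42 ± 0.16), the atrial list (1 and 2 of 8, median −0.18, turning to 0.04 with edgeR), the neural list (1 and 0 of 4), the circadian list (4 and 7 of 15, 6 and 4 after median centring, Per2 at −1.68 ± 0.17 and Arntl at 1.08 ± 0.14) and the immediate early list (3 and 5 of 14, median −0.21, turning to 0.06 with edgeR). All 4 tested Y-linked genes fell (4 adjusted over the list alone; list adjusted p = 0.0314; adjusted p = 0.433 with an estimated correlation). Eif2s3y lay at 38.3 ± 2.81 FPKM at E18, 40.9 ± 20.6 at 3d and 0.764 ± 0.892 at 8w, and Uty was at −3.25 ± 0.39 and Ddx3y at −2.64 ± 0.45 on the log2 scale. The sex of the animals is not given in the sources used here.

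At this step 6971 of 11930 coding genes passed limma, 2550 higher and 4421 lower, and 15 of 30 lists passed camera. The split was 3298 and 3297 after quantile normalization, 3378 and 3187 after median centring and 3612 and 3534 with edgeR on the estimated counts. With an estimated correlation 2 lists kept their call, those of the adult sarcomere and of fatty acid oxidation.

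**Figure D2:**
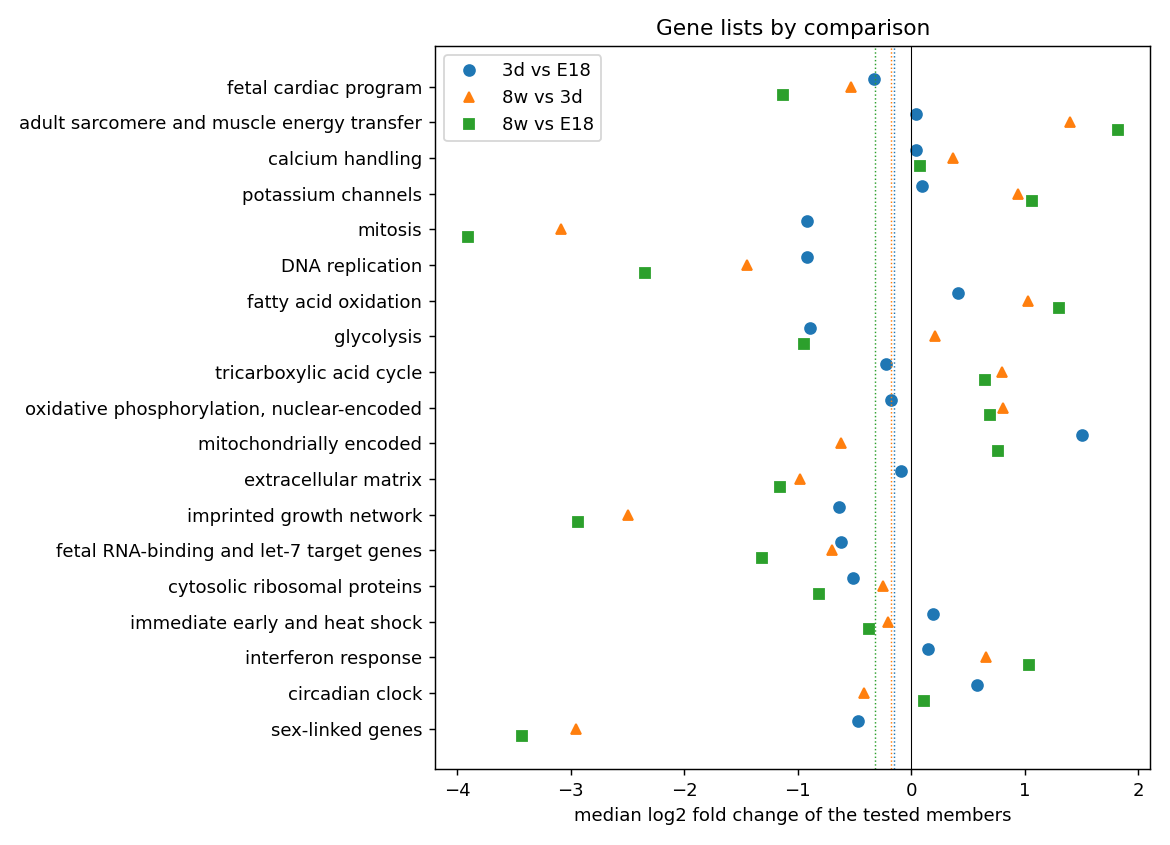
Median log2 fold change of the tested members of each process list in the 3 comparisons; dotted lines mark the median of all 11930 tested genes and the solid line marks 0. The mitosis list goes from −0.92 at the first step to −3.09 at the second, and the adult sarcomere list from 0.04 to 1.4.

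H19 fell from 789 ± 134 to 12.4 ± 1.83 FPKM (SD, n = 3; log2 fold change −5.88 ± 0.17 SE, adjusted p = 9.08e-07). Meg3 (−2.95 ± 0.31), Rian (−2.40 ± 0.14), Airn (−1.94 ± 0.17) and Kcnq1ot1 (−0.78 ± 0.12), which come from imprinted regions, fell on the log2 scale as well, and Neat1 rose by 1.46 ± 0.18. Malat1 fell by 0.56 (SE 0.16, adjusted p = 0.0294), a call that ended under median centring, with edgeR and without any single library other than E18 replicate 2. Xist had −0.62 ± 0.32, which did not pass. Of the entries named after coding genes, Vash2 was at −3.11 ± 0.11 and Plet1os, an antisense transcript, at 3.04 ± 0.22; their reads cannot be told from those of the coding partner without strand. Of 3635 lncRNA genes 1328 passed limma, 289 higher and 1039 lower, a split of 482 and 558 after quantile normalization, 393 and 668 after median centring and 498 and 554 with edgeR. Entries overlapping a coding exon in sense, which could share its reads, were 1118 of those tested. They gave 329 of the limma calls, 85 higher and 244 lower.

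Titin circRNAs changed in both directions between 3d and 8w. The circle of exons 87 to 120 rose from 62 to 533 reads, 6.60-fold (95% counting interval 5.07 to 8.74), and that of exons 86 to 120 (chromosome 2, 76857904 to 76884197) from 47 to 493 reads, 8.06-fold (5.97 to 11.1, edgeR adjusted p = 1.57e-27). The circle of exons 125 to 129 (76853605 to 76856366) went from 57 reads to 0, at least 24.7-fold lower (adjusted p = 1.65e-12). The circle of exons 120 to 142 (76847388 to 76857987) went from 30 reads to 0, at least 13-fold lower (adjusted p = 2.82e-06), with 3 reads over the group as the floor for 0. All titin circles together took 3.2% ± 0.3 of junction reads at E18, 5.0% ± 0.4 at 3d and 11.5% ± 1.6 at 8w (SD, n = 3). Exact two-sided permutation tests gave p = 0.1 for each pair of stages, the smallest value that 3 against 3 can give.

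**Figure D3:**
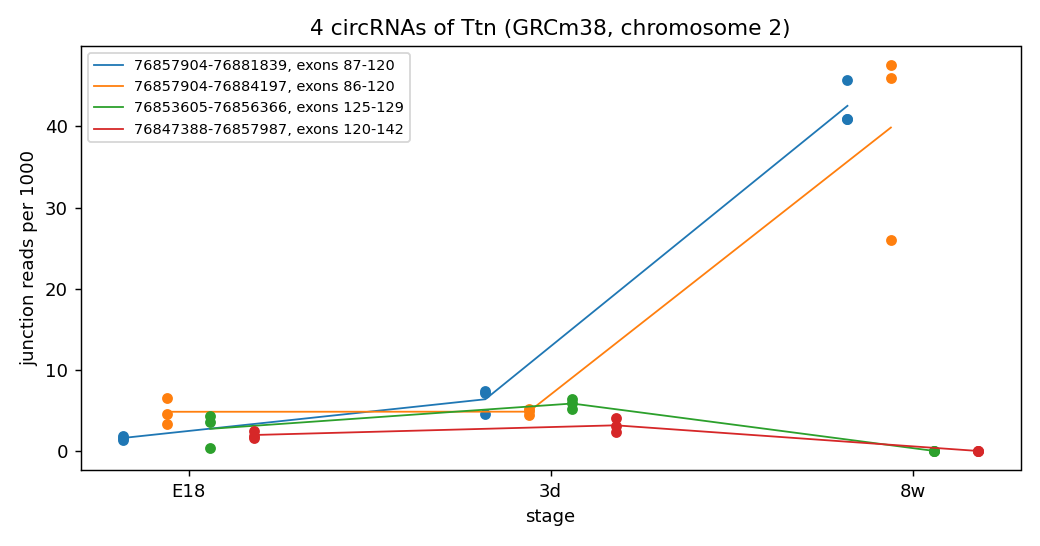
Junction reads per 1000 junction reads of the library for 4 titin circRNAs by stage; each dot is a library and lines join the means. At 8w the circles of exons 87 to 120 and 86 to 120, with 533 and 493 reads, stand above the others shown, and the circles of exons 125 to 129 and 120 to 142 are at 0 in the 3 libraries of 8w.

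Cacna1d exons 2 to 3 (chromosome 14, 30346798 to 30350949) went from 18 reads to 0, at least 7.81-fold lower, a call that ended without 3d replicate 3. Ube2k went from 22 reads to 3, 9.55-fold lower (2.87 to 49.8), and Zfp827 from 21 to 3, 9.11-fold lower (2.72 to 47.7). Circles of Agtpbp1 exons 2 to 11 (0 to 20 reads, at least 5.12-fold higher), Cpeb3 (1 to 24, 18.4-fold, 3.01 to 758), Kcnt2 (1 to 21, 16.1-fold, 2.59 to 667) and the Mb locus (4 to 48, 9.22-fold, 3.38 to 35.2) rose. These calls ended when a single library was left out: 3d replicate 1, 2 or 3 or 8w replicate 2 for Agtpbp1, and 3d replicate 1, 2 or 3 or 8w replicate 3 for Cpeb3. For Kcnt2 these were E18 replicate 2 or 3, 3d replicate 1, 2 or 3 and 8w replicate 1 or 2, and for Mb 3d replicate 3 or 8w replicate 2. For Ube2k they were E18 replicate 3, 3d replicate 2 or 3 and 8w replicate 3, and for Zfp827 3d replicate 1 or 3 and 8w replicate 1 or 2. In all 18 of 626 circRNAs passed edgeR, 8 higher and 10 lower, with 5 and 13 when library size was used without TMM factors. The count was 7 without 3d replicate 3.

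Over the whole interval from E18 to 8w, Tnni1 and Myh7 were lower and Myh6 and genes of fat oxidation higher, while glycolysis genes went both ways. Tnni1 fell from 794 ± 16.6 to 2.47 ± 1.72 FPKM (SD, n = 3; log2 fold change −8.00 ± 0.35 SE, adjusted p = 1.78e-08), and Myh7 by 6.42 on the log2 scale (SE 0.17) from 1920 ± 112 FPKM. Myh6 (chromosome 14, 54941921 to 54966927) rose from 1130 ± 254 to 6770 ± 777 FPKM. Its log2 fold change was 2.59 ± 0.20 (SE, adjusted p = 1.24e-06). Ces1d (5.61 ± 0.20), Tuba8 (5.50 ± 0.21), Rpl3l (5.39 ± 0.23), Art1 (5.10 ± 0.13), Xirp2 (5.06 ± 0.12), Cd74 (4.83 ± 0.19) and the membrane repair protein Trim72 (4.61 ± 0.13) rose most on the log2 scale. Mest (−5.89 ± 0.23), Dlk1 (−5.76 ± 0.14), Bex4 (−5.73 ± 0.15), Igf2 (−5.59 ± 0.18) and the cyclin-dependent kinase partner Cks2 (−5.52 ± 0.28) fell most after Tnni1 and Myh7, apart from mt-Co1, which was listed at 0.

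Of 18 adult sarcomere genes 16 rose (17 adjusted over the list alone; 14 after quantile normalization), with the titin cap protein Tcap at 3.08 ± 0.17 (list adjusted p = 1.48e-13, and 0.00502 with an estimated correlation). All 26 fatty acid oxidation genes rose (26 adjusted over the list alone), with Pdk4, which shuts off pyruvate oxidation, from 22.6 ± 2.93 to 474 ± 319 FPKM (list adjusted p = 1.15e-19, and 0.006 with an estimated correlation). Of 14 fetal cardiac program genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; list adjusted p = 0.174). Fry, which compares with no change, called the fetal list lower (adjusted p = 3.65e-05). Glycolysis genes had 7 risen and 13 fallen of 22 (7 and 13 adjusted over the list alone; list adjusted p = 0.674), with Slc2a4 at 2.37 ± 0.12 and Slc2a1 at −3.03 ± 0.10. Oxidative phosphorylation genes rose in 39 of 45 cases (39 adjusted over the list alone; 31 after quantile normalization; list adjusted p = 1.48e-16, and 0.0425 with an estimated correlation). Potassium channels had 11 risen and 2 fallen of 16 (11 and 2 adjusted over the list alone) and macrophage markers 8 risen of 11 (8 adjusted over the list alone), both with adjusted p = 0.0425 with an estimated correlation. Cardiomyocyte markers had 6 risen and 0 fallen of 11 (6 and 0 adjusted over the list alone), but 5 risen and 3 fallen after quantile normalization, where their median turned from 0.47 to −0.05. All 30 mitosis and all 30 DNA replication genes fell (30 and 30 adjusted over the list alone; adjusted p = 0.126 and 0.0649 with an estimated correlation), with survivin, Birc5, at −4.63 ± 0.11 and the helicase subunit Mcm6 at −3.03 ± 0.10. Ribosomal protein genes fell in 38 of 43 cases (39 adjusted over the list alone; list adjusted p = 1.56e-05; adjusted p = 0.316 with an estimated correlation). All 7 tested epicardial markers fell (7 adjusted over the list alone; list adjusted p = 0.0104; adjusted p = 0.0838 with an estimated correlation). Of 9 erythroid markers 8 fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.0815), with the globin Hbb-bt at −1.94 ± 0.24, and Hbb-y was listed at 0 FPKM at 8w. Genes encoded on mitochondrial DNA had 5 risen and 1 at 0, mt-Co1, of 11 (5 and 1 adjusted over the list alone; 1 risen after quantile normalization; list adjusted p = 0.124), and their median was 0.76 and their mean −1.38. The zeros of mt-Co1, and those of mt-Atp6, mt-Co3, mt-Nd3, mt-Nd4 and mt-Nd4l in 8w replicate 1, enter that mean and these calls.

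Among coding genes 7761 of 11930 passed limma, 2120 higher and 5641 lower, and 21 of 30 lists passed camera, 6 of them with an estimated correlation. The split was 3410 and 3407 after quantile normalization, 3665 and 3185 after median centring and 3878 and 3565 with edgeR. Among lncRNAs H19 fell by 6.72 (SE 0.17, adjusted p = 1.65e-07), Rian by 3.45 (SE 0.14) and Meg3 by 3.17 (SE 0.31) on the log2 scale, and Neat1 rose by 3.21 (SE 0.18). Of 3635 lncRNA genes 1336 passed, 279 higher and 1057 lower, against 476 and 537 after quantile normalization, 532 and 468 after median centring and 478 and 542 with edgeR. Entries overlapping a coding exon in sense gave 372 of the 1336 calls. Of 626 circRNAs 37 passed edgeR, 17 higher and 20 lower, and 12 and 6 with DESeq2. The count was 13, 19 or 18 without E18 replicate 1, 2 or 3, and 14 without 8w replicate 3. The Ttn circle of exons 87 to 120 was 26.6-fold higher at 8w than at E18 (95% counting interval 16.5 to 46.1), and that of exons 125 to 129 at least 11.8-fold lower. Rbp7 reads (16 at 8w, 0 at E18) came from 8w replicate 1 alone, and the fitted log2 fold change was 0 without it. The circle of Casc5, a kinetochore gene, went from 13 reads to 0, at least 5.1-fold lower, a call that ended without E18 replicate 1, 2 or 3 or without 8w replicate 1, 2 or 3.

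The consecutive steps could be compared directly. A camera test of the difference between them passed for the adult sarcomere list, whose rise was larger at the second step (adjusted p = 2.42e-07, and 0.0305 with an estimated correlation). The mitosis list fell further at the second step (adjusted p = 7.77e-18; adjusted p = 0.15 with an estimated correlation). Of 11930 genes 1059 fell at both steps, 236 rose at both, 590 fell and then rose, and 201 rose and then fell, against 948, 127, 547 and 221 for independent lists. These classes hold on the deposited scale, where lower calls prevail; under median centring 1146 genes were higher and 997 lower at the first step, and 3378 and 3187 at the second. Simulations without effects gave 0 called in both, which sets no level for the overlap of steps that hold effects. Across genes the log2 fold changes of the steps had a correlation of 0.14 and a covariance of 0.047, beside −0.502 and −0.0193 in 50 simulations without effects. Genes are not independent replicates. Both steps share the 3 libraries at 3d, which pushes their changes apart in sign, so part of the genes that fell and then rose may come from the shared libraries.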

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

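EdgeR on recovered fragments, library size from fragments, and median centring of lists and named genes were chosen after the data were seen. Total counts stayed within 1.5 times under quantile normalization, median centring, edgeR, pseudocount 0.1, limma without trend and no filter on low FPKM, where these applied. The split by direction did not. Under median centring at 3d against E18, coding calls went from 596 higher and 2557 lower to 1146 and 997. The lncRNA calls went from 75 higher and 81 lower to 184 and 44. A 2-fold minimum left 250, 2079 and 2749 coding genes and 56, 533 and 588 lncRNAs (3d vs E18, 8w vs 3d, 8w vs E18), fewer by construction. With only the libraries of the 2 stages, which leaves fewer samples, 102 lncRNAs (3d vs E18) and 22 circRNAs (8w vs E18) passed. A mean FPKM of at least 2 gave 759 and 795 lncRNAs (8w vs 3d, 8w vs E18), fewer being tested. No filter gave 10 and 14 circRNAs in the same comparisons, and DESeq2 18 in 8w vs E18; the cause was not tested. Estimated correlation left 3, 2 and 6 lists, and fry called 24 in 8w vs 3d. With the replicate block, 2686, 6750 and 7575 coding genes and 61 lncRNAs (3d vs E18) passed.

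Leaving out 1 library gave 1823 to 3339, 6171 to 6881 and 6938 to 8191 coding genes, 22 to 157, 1037 to 1273 and 1073 to 1423 lncRNAs, 2 to 2, 7 to 18 and 13 to 34 circRNAs, and 16 to 20, 15 to 16 and 19 to 22 lists. Directions reversed with fry for the circadian clock list in 8w vs 3d (0.0469) and, in 8w vs E18, the mitochondrially encoded (1.09e-05) and ventricular marker lists (0.000887). The log2 fold change of the Rbp7 circRNA in 8w vs E18 went to 0 without 8w replicate 1 and 6.02 without 8w replicate 3. None of the lists that reversed with fry had passed camera there (adjusted p = 0.792, 0.124 and 0.944), so camera had called no direction for them. Camera compares members with the other genes and fry with no change, so their directions can differ. Over the comparisons fry added a call for 15 list results and dropped it for 5. Beyond this the cause was not tested for fry. The mitochondrially encoded list, however, holds mt-Co1, listed at 0 in every library of 8w, and 5 genes at 0 in 8w replicate 1. Its median in 8w vs E18 was 0.76 and its mean −1.38, so these zeros weigh on its direction. The Rbp7 reads lie in 8w replicate 1 alone. Of named-gene values, quantile normalization kept 376 calls or non-calls and weakened 29, and leaving out libraries 3574 and 264. The 10-fold pseudocount for circRNAs was not run, since the column holds counts. The 2676 to 4494 junction reads per library limit what circRNA changes can be seen.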

Other observations

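The tests on genes listed at 0 and on Xist, the splits of the libraries, and the gene families of the next paragraph were chosen only after the results were seen.

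Histone genes, MHC genes and glutathione transferases were chosen after their values were seen, from pathway counts. Of 70 histone genes 34 fell at 3d against E18 and 67 at 8w against 3d, with Hist1h1b at −3.85 ± 0.12 in the latter (SE, limma adjusted p = 6.99e-09). All 5 MHC class II genes rose at 8w against 3d, with H2-Aa at 3.47 ± 0.21 (adjusted p = 3.06e-07), and so did all 7 class I genes. Of 16 glutathione transferase genes 12 rose, with Gstm1 at 1.11 ± 0.09 (adjusted p = 3.52e-06). Members of these families are similar in sequence, so single values are uncertain. KEGG pathways of genes changed at least 2-fold were tested with a hypergeometric test over 265 pathways. At 3d against E18, 10 passed as lower and 3 as higher. The first of each were cell cycle, with 15 of 114 genes fallen (adjusted p = 3.35e-06), and PPAR signalling, with 6 of 46 risen (adjusted p = 0.000486). That test treats genes as independent, so its p-values do not measure spread between libraries.

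Some abundant genes were listed at 0. Ttn had 0 fragments in all 9 libraries, although its lowest number of junction reads in a library was 95, which argues against an absence of Ttn RNA. On the mitochondrial chromosome, 5 of the 5 coding genes between 7765 and 11544 that were above 0 in another library were at 0 in 8w replicate 1, as were the lncRNA entries AK141672, AK141702 and Atpase6 there, so the authors' estimation may have skipped whole loci in a library. In 3d replicate 1, however, mt-Atp6 was at 0 while mt-Nd4 and mt-Co3 of the same locus had 71311 and 7308 fragments. Not every 0 was thus shared by a whole locus. The locus of mt-Co1 (5326 to 6938) was at 0 in all 3 libraries of 8w, and so were the lncRNA entries DQ539915 and AK140152 of that locus, the former with 9964 to 12278 fragments at 3d. Its neighbour mt-Nd2 kept 32704 to 69800 fragments at 8w, and mt-Cytb 111332 to 197001. These values go against a loss of mitochondrial RNA as a whole, and a skipped locus may lie behind these zeros as well.

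Y-linked genes were near 0 at 8w. Their 4 X-linked copies had a median log2 fold change of −0.23 in 8w against 3d (Ddx3x −0.32, Kdm5c −0.26, Eif2s3x 0.28, Kdm6a −0.21), which argues against a fall of these families on both sex chromosomes. The ratio of mean Xist FPKM between 8w and E18 was 0.86, so Xist was not higher at 8w. A fall of Xist with age could hide a higher share of females, so this ratio cannot decide on sex. A different sex of the animals at 8w could lower Y-linked genes, and Xist was present at all stages. All 4 tested Y-linked genes fell at 8w against 3d, with a median log2 fold change of −2.95. That fall by itself goes with a different sex makeup of the 8w libraries. Neither Xist nor the X-linked copies, none of which rose strongly at 8w, add to that reading. Sex is not given in the sources used here, so the comparisons with 8w may mix it with stage. Eif2s3y also had a larger SD at 3d than at E18, so the 3d libraries may differ in sex among themselves. A share of sex in 3d against E18 cannot be told apart either.

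The median coding gene was lower at the later stage on the deposited scale. Dividing libraries by fragments outside their 20 largest genes took the medians from −0.154, −0.177 and −0.324 to −0.055, −0.121 and −0.177 (3d against E18, 8w against 3d, 8w against E18). Outside the 100 largest genes they were −0.05, −0.077 and −0.128, and with total fragments −0.129, −0.1 and −0.231. Neither abundant genes nor the authors' factors account for the whole of the shift. A change in RNA composition with age may remain and was not tested.

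Changes of circRNAs may in part follow their host gene. Across 588 circRNAs of 431 hosts, Spearman rho between the log2 fold changes was 0.374 in 8w against E18, 0.283 in 8w against 3d and 0.157 in 3d against E18. Permutation p was 2e-05, the smallest the permutations can give, for the first 2, and 0.00012 for the third. Circles of Ttn are not among them, since Ttn was listed at 0 and has no fold change of its own. Genes are not independent replicates.

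The 10 splits of 6 libraries were too few for a share under 0.05. All but the real split put libraries of both stages in the same group. Stage differences then add to the spread within groups, so low gene counts follow from the design and are no evidence against chance. The real split and the highest other gave 3153 and 0, 6971 and 2, and 7761 and 0 coding genes (3d against E18, 8w against 3d, 8w against E18). For lncRNAs they gave 156 and 3, 1328 and 4, and 1336 and 1, and for circRNAs 2 and 0, 18 and 1, and 37 and 2. For lists they gave 19 and 14, 15 and 18, and 21 and 19. In each case 1 split reached the real value, the real split itself, except lists in 8w against 3d, where 4 did.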
